A study of Mus musculus with 18 samples.

How the data were processed

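The study measured gene expression in mouse dermal cells sorted by a Cre-driven lineage reporter, with Affymetrix Mouse Genome 430 2.0 arrays, 18 arrays in 6 groups of 3. Groups and replicate numbers were taken from the sample titles. In the R26mTmG reporter, cells carry red fluorescence until Cre recombination switches them and their descendants to green fluorescence. Per the labels, ENF (red, not green) and EPF (green, not red) cells came from dorsal dermis of En1Cre; R26mTmG mice, Dorsal and Ventral cells were green cells of the same line, and Cranial and Oral cells were green cells of Wnt1Cre; R26mTmG mice. Per the labels, every sample was sorted as negative for CD31, CD45, Tie2, a marker written Tie119, EpCAM and DAPI. The labels give postnatal day 56 for ENF and EPF and postnatal day 30 for the other 4 groups, while the protocol text gives 30 days for back skin; which holds for ENF and EPF is not settled by the sources used here.

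Per the labels' protocols, RNA was extracted with phenol and chloroform, cleaned on columns and converted to cDNA with SuperScript III before hybridization. Per the series design text and the submitters' processing notes, the authors normalized the arrays by RMA with quantile normalization in R and deposited log2 expression values, 1 column per array. The software versions, and whether the 18 arrays were normalized in 1 run, are not given in the sources used here. The deposited columns did not share 1 distribution of values. RMA normalizes probe intensities before combining them into probe sets, so this cannot tell whether 1 run was made. The authors also clustered the arrays with AutoSOME, per the series design text; that clustering was not run here.

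The deposited table held 45101 probe sets. After 64 control probe sets were set aside, 45037 remained, of which 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 none. Of the probe sets with 1 symbol, 34741 matched a gene of the mouse GRCm38.p6 gene table by Entrez identifier, and 0 symbols needed an update. That table served for names only, and no coordinates are given because the arrays' values carry none. For each of 18193 genes the probe set with the highest mean over the 18 arrays was used; 9010 genes had more than 1 single-gene probe set. Probe sets with several or no symbols were left out of the tests per gene.

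Differences between groups were tested on the log2 values with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all 18193 genes, and a gene was called at an adjusted p under 0.05. No dim probe sets were removed. EPF and ENF were fitted on their 6 arrays, the 4 site groups on their 12 arrays in 1 fit that shared the estimate of spread, and EPF and Dorsal on their 6 arrays. Values are log2 means ± SD of 3 arrays, and differences are log2 differences ± SE from limma. The 27 gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. For each list the number of called members was also taken after adjustment over the list alone. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and drew the plots.

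The 27 lists covered collagens, matrix glycoproteins and crosslinkers, small leucine-rich proteoglycans, matrix proteases and inhibitors, Hox genes, craniofacial patterning factors, trunk dermis patterning factors, the Wnt pathway, the TGF-beta and BMP pathway, chemokines with cytokines and complement, immediate early and stress genes, cell cycle genes, papillary dermis fibroblasts, and reticular and hypodermal fibroblasts. They also covered markers of fibroblasts in general, keratinocytes, endothelial cells, leukocytes, mural and smooth muscle cells, skeletal muscle, Schwann cells, melanocytes, the adipocyte lineage, osteoblasts with cartilage and tooth mesenchyme, tendon and ligament, dermal papilla and dermal sheath, and erythroid cells. Members with no single-gene probe set here were left out of the lists, which left 5 of 10 erythroid genes and 14 of 18 bone, cartilage and tooth genes. Names were also matched through synonyms, by which Sca1, meant as Ly6a, was wrongly matched to Atxn1 in the reticular list; it was kept there, and leaving it out was added as an alternative. Ly6a itself has no single-gene probe set here. The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. In the 4 main comparisons the rule named the 8 called genes with the largest rise and the 8 with the largest fall among those whose arrays did not overlap between groups, up to 2 called members per list and direction (or the members with the largest difference where none was called), and En1, Dpp4, Pecam1, Ptprc, Tek, Epcam, Pdgfra and Acta2. In the other comparisons it named 3 genes per direction. Genes named outside this rule are said to be chosen after their values were seen.

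The fits were tested on simulated data of 18193 genes, in which 100 genes differed by 1 and 100 by 2 on the log2 scale. Each gene had its real mean and pooled spread, with normal noise of equal size in every group and independent between genes. In the simulation of EPF against ENF, 38 genes of the smaller and 87 of the larger change were called, with 5 of 17993 unchanged genes. For Oral against Cranial these were 68, 91 and 11, for Ventral against Dorsal 54, 96 and 4, and for Cranial against Dorsal 65, 94 and 8. The real groups differed in spread and no correlation between genes was simulated, so these numbers do not give error rates on the real data. Arrays give no read depth, so the number of arrays, 3 per group, limits the precision. Nothing in the labels says that arrays of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The site groups shared 1 estimate of spread but differed in it. Their median SD per gene was 0.281 in Dorsal, 0.141 in Ventral, 0.134 in Oral and 0.104 in Cranial. The shared estimate tends to overstate the spread of Oral and Cranial and to understate that of Dorsal. A gene not called for Oral against Cranial may therefore still differ.

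The alternatives were quantile normalization repeated on the deposited values, centring each array on its median, leaving out the 40% of genes with the lowest mean, testing every probe set, averaging the probe sets of a gene, an intensity trend with robust eBayes, array weights, all 18 arrays or only the 2 groups in the fit, a 2-fold minimum, the replicate number as a block, an estimated inter-gene correlation, and leaving out each array in turn. Leaving out 2 arrays with little Xist signal, a covariate for the level of keratinocyte genes, and leaving Atxn1 out of its list were added after the data had been seen. Median levels of genes differed between groups by 0.21 (Cranial minus Dorsal), 0.20 (Oral minus Dorsal), 0.18 (Cranial minus Ventral), 0.17 (Oral minus Ventral) and 0.16 (EPF minus Dorsal) on the log2 scale. The median difference per gene was smaller in size, at -0.06, -0.02, -0.06, -0.02 and 0.01 in the same order. Centring takes out the shift of the medians and so moves every difference per gene downward in these comparisons. The directions of small differences there depend on the scaling.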

Results

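Expression was measured in 18 arrays of sorted mouse dermal cells, 3 each of ENF, EPF, Cranial, Oral, Dorsal and Ventral. ENF and EPF cells separate dorsal dermis by whether the cells descend from cells that expressed Engrailed-1, a homeobox factor of embryonic patterning. Cranial and Oral cells descend from Wnt1-expressing cells, which include the neural crest. All values are log2 expression after RMA. A group mean at or below the lower quartile of the arrays (3.93 to 4.10) is near background, so a difference from it is a lower bound and ranks by size are uncertain there. With 3 arrays per group, the number of arrays limits the precision. No array was identical to another, and the closest pair, Cranial 1 and Cranial 2, correlated at r = 0.998 across genes.

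The arrays fell into 2 sets. Correlations across genes ran from 0.962 to 0.988 within the EPF and ENF arrays, from 0.946 to 0.998 within the site arrays, and from 0.872 to 0.926 across the sets. The first principal component, with 58.3% of the variance, parted the EPF and ENF arrays from the site arrays, and the second, with 13.7%, parted Cranial and Oral from Dorsal and Ventral. The third held 6.33% and ran from 71.5 in Dorsal 1 to -31.2 in Dorsal 3. Arrays differed most within Dorsal, with a median SD per gene of 0.281, against 0.249 in ENF, 0.184 in EPF, 0.141 in Ventral, 0.134 in Oral and 0.104 in Cranial.

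**Figure D1:**
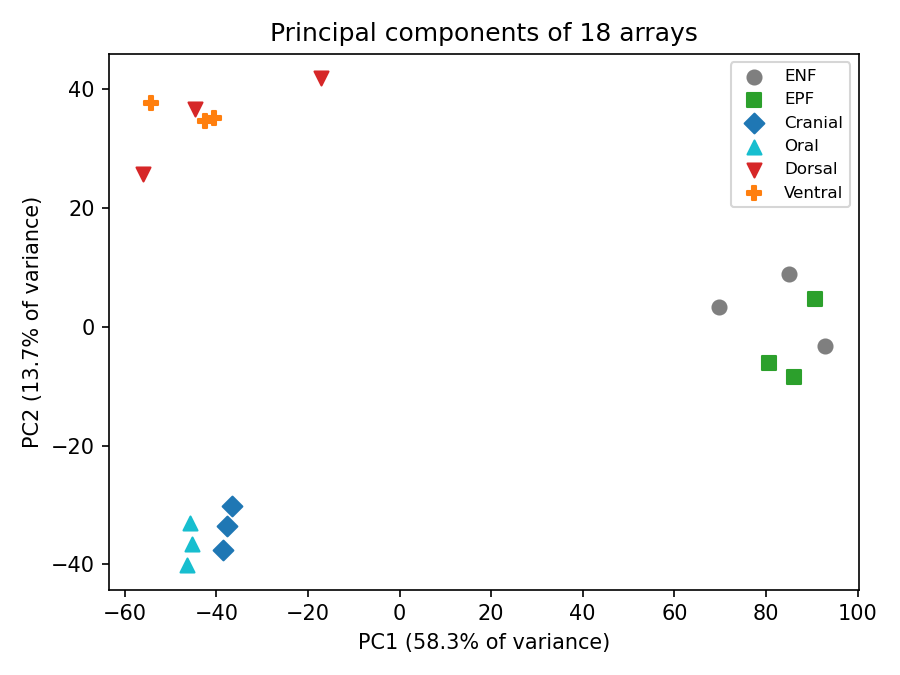
First and second principal component of the 18 arrays, each point 1 array, with axes in component units and the share of variance on each axis (58.3% and 13.7%). EPF and ENF arrays lie at 69.8 to 92.8 on the first component and the site arrays at -55.9 to -17.1, while Cranial and Oral lie at -40.2 to -30.1 and Dorsal and Ventral at 25.7 to 41.9 on the second.

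Genes of the sort gate and of known fibroblast subsets described the cells first. Pdgfra, a receptor found on dermal fibroblasts, was at 13.17 ± 0.19 in EPF and 13.09 ± 0.08 in ENF and between 11.53 ± 0.72 and 12.39 ± 0.16 in the site groups (SD, n = 3). Dpp4, which encodes the surface protease CD26, was at 11.36 ± 0.79 in EPF and 11.73 ± 0.05 in ENF, and at 4.51 to 4.80 in the site groups. En1 itself was near the dim end of the arrays in every group, from 3.41 in Oral to 4.06 in Cranial. Pecam1, the gene of CD31, stayed between 3.77 and 4.09, and Ptprc, the gene of CD45, between 3.82 and 4.21. Tek, which encodes Tie2, had means of 10.20 in EPF and 10.46 in ENF although both were sorted as Tie2 negative, and at 3.75 to 4.27 in the site groups. The Epcam probe set used was at 8.43 to 9.11 in all 6 groups, while the other was at 8.25 ± 1.83 in ENF, 5.65 ± 1.58 in EPF and 4.42 to 5.15 in the site groups, and was not called for EPF against ENF (-2.60), so the 2 probe sets disagree on the gene. None of En1, Dpp4, Pecam1, Ptprc, Tek, Epcam and Pdgfra was called in any of the 4 main comparisons by limma, with adjusted p from 0.0642 for En1 in Oral against Cranial upward.

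The first comparison asked how Engrailed-lineage cells of the back differ from the other dermal cells sorted from it. Levels of control probe sets also parted these groups, so any difference in array handling coincides with the comparison. Zic1, a zinc finger factor of dorsal mesoderm, was 22.0-fold higher in EPF, at 10.93 ± 0.19 against 6.47 ± 0.39 in ENF (log2 difference 4.46 ± 0.23, SE, n = 3 per group). Ednrb, an endothelin receptor, was higher by 4.70 ± 0.52 and Mylk, myosin light chain kinase, by 3.73 ± 0.16. Col11a1, a fibrillar collagen, was higher by 3.55 ± 0.46 (ENF near background, at 3.93), Igfbp2 by 3.52 ± 0.28, Ctla2a by 3.48 ± 0.44, Tnmd, a tendon membrane protein, by 3.48 ± 0.48, and Mfap4, a microfibril protein, by 3.38 ± 0.28. On the other side, Myf5, a factor of the skeletal muscle lineage, was lower in EPF (2.92 ± 0.08, near background, against 7.89 ± 0.98), and Trp63, a master factor of stratified epithelium, fell by 4.13 on the log2 scale. Adjusted p in limma ran from 0.000371 for Mylk to 0.0461 for Lhx2, and in every called gene named here all 3 arrays of one group lay above all 3 of the other. The rule that named the leading genes required this, so it is no further support for them.

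In all, 56 of 18193 genes were called, 50 higher and 6 lower in EPF, and all 56 differed by at least 2-fold. The 6 lower genes were Myf5, Trp63, Lhx2 (fell by 3.38, EPF near background at 4.01, called in 9 of 18 settings), Lypd3 (fell by 2.72), Acta1 (fell by 2.35) and Chrdl2 (fell by 2.20). Without regard to multiple tests, 1967 genes had p under 0.05, and the groups did not overlap in 3100 of 18193 genes, against 10% by chance. The count rested on single arrays, at 130 without ENF 3, 37 without EPF 1, 4 without EPF 2 and 9 without EPF 3, and it was 460 with all 18 arrays in the fit and 88 with an intensity trend and robust eBayes together. The balance of directions varied too, with 268 higher and 192 lower with all 18 arrays, 42 and 32 without ENF 1, and 71 and 59 without ENF 3. ENF 1 and EPF 2 stood apart in Xist, the RNA of the inactive X chromosome and chosen after its values were seen, at 4.98 and 5.20 against 11.60 to 12.13 in the other 4 arrays, and without both 4 genes were called, 2 higher and 2 lower.

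Smooth muscle genes made up the clearest group. Of 18 mural and smooth muscle genes 4 were higher in EPF and 14 were not called, while adjusted over the list alone 14 were higher. Actg2, smooth muscle gamma actin, was higher by 2.65 ± 0.24, Myh11, the smooth muscle myosin heavy chain, by 2.29 ± 0.17, Cnn1 by 2.13 ± 0.25 and Acta2, smooth muscle alpha actin, by 1.67 ± 0.20 (12.60 ± 0.06 against 10.93 ± 0.34). Over the settings Actg2 was called in 15 of 19, Myh11 in 16 of 18, Cnn1 in 13 of 19 and Acta2 in 12 of 19. Their adjusted p in limma reached 0.1647, 0.1025, 0.2639 and 0.2655. The pericyte gene Rgs5, chosen after its values were seen, was not called, at 11.83 ± 0.50 in EPF and 8.76 ± 1.00 in ENF (adjusted p = 0.0637). The list rose as a whole by camera (median difference 1.16, adjusted p = 5.60e-19), and it was the 1 list of 17 called ones that held with an estimated correlation (adjusted p = 0.0150). Among 18 dermal papilla and dermal sheath genes 1 was higher and 17 were not called (7 higher adjusted over the list alone), with a median of 0.95 and adjusted p = 9.04e-10. With an estimated correlation that p was 0.0647.

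Camera called the matrix and tendon lists higher in EPF at the preset correlation alone, with few members called. Of 10 tendon and ligament genes 3 were higher and 7 not called (4 adjusted over the list alone), among them Tnmd, Mkx, a tendon homeobox factor, by 2.29 ± 0.19, and Thbs4, a matrix thrombospondin, by 2.17 ± 0.31. Tnmd was called in 9 of 19 settings and Thbs4 in 7 of 19 (adjusted p up to 0.196 and 0.259), so the tendon and glycoprotein counts rest on calls that often did not hold. Of 25 collagens 2 were higher and 23 not called (4 adjusted over the list alone), Col11a1 and Col23a1 (2.18 ± 0.20). Of 29 matrix glycoproteins and crosslinkers 2 were higher and 27 not called (8 adjusted over the list alone), Mfap4 and Thbs4. No member was called among 12 small leucine-rich proteoglycans (2 adjusted over the list alone) or 27 proteases and inhibitors (5 adjusted over the list alone), where Fmod stood at 10.34 ± 0.19 against 7.40 ± 1.39 and Mmp11 at 10.01 ± 0.91 against 8.08 ± 0.40. Camera called these 5 lists higher at adjusted p of 0.000192 for tendon, 6.76e-08 for collagens, 1.24e-05 for glycoproteins, 0.00163 for proteoglycans and 0.000192 for proteases. With an estimated correlation the adjusted p was 0.126 for tendon and proteoglycans and 0.0943 for the other 3.

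Camera also called signalling, stress response, melanocyte and fibroblast lists higher at the preset correlation alone, with few members called. Of 34 Wnt pathway genes 1 was higher, Dkk2, a secreted Wnt antagonist, by 2.47 ± 0.28, and 8 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000192; 0.0921 with an estimated correlation). Of 31 TGF-beta and BMP genes 1 was higher, Inhba, an activin subunit, by 1.74 ± 0.22, which was also the 1 adjusted over the list alone (camera adjusted p = 0.000780; 0.211 with an estimated correlation). Of 32 immediate early and stress genes 1 was higher, Nr4a3, by 1.38 ± 0.17, and 4 adjusted over the list alone (8.22e-06; 0.147 with an estimated correlation). Of 17 reticular and hypodermal genes 3 were higher, Ppp1r14a, an inhibitor of myosin phosphatase, by 3.38 ± 0.25, with Cnn1 and Acta2, which are also on the smooth muscle list (4 adjusted over the list alone; camera adjusted p = 0.000192; 0.126 with an estimated correlation). That list holds Atxn1 by a wrong match of the name Sca1; without it the median moved from 0.27 to 0.15 and the adjusted p were 0.000559 and 0.147. Of 14 papillary genes none was called and 3 were higher adjusted over the list alone, Crabp1 standing at 8.81 ± 0.25 against 5.72 ± 1.11 (0.000267; 0.0943 with an estimated correlation). Of 15 general fibroblast genes none was called and 1 was higher adjusted over the list alone, Fbln1 standing at 11.12 ± 0.06 against 10.07 ± 0.38 (0.00376; 0.211 with an estimated correlation). Of 11 melanocyte genes none was called and 1 was higher adjusted over the list alone, Mlana standing at 8.69 ± 1.04 against 6.43 ± 0.49 (0.0451; 0.211 with an estimated correlation).

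Camera called the keratinocyte, cell cycle and skeletal muscle lists lower in EPF at the preset correlation alone. Of 19 keratinocyte and hair follicle genes 1 was lower, Trp63, and 18 were not called (4 lower adjusted over the list alone), with a median difference of -2.40. Krt14, a keratin of basal keratinocytes, and Perp, a desmosome gene, were chosen after their values were seen. Krt14 was not called, at 5.80, 9.81 and 9.54 in ENF 1 to 3 and 6.30, 4.48 and 5.29 in EPF 1 to 3, and Perp ranged from 3.95 in EPF 2 to 13.30 in ENF 3. Of 31 cell cycle genes none was called and 6 were lower adjusted over the list alone, with a median of -1.03; Mki67, a marker of dividing cells, was at 5.58 ± 1.17 in EPF and 7.91 ± 1.66 in ENF, and Rrm2 at 6.83 ± 0.60 and 9.41 ± 1.56. Of 22 skeletal muscle genes 2 were lower, Myf5 and Acta1, and 20 not called (4 lower adjusted over the list alone), with a median of -0.24. The camera adjusted p was 1.55e-06 for keratinocytes, 6.05e-14 for the cell cycle and 4.32e-05 for skeletal muscle, and with an estimated correlation it was 0.211, 0.211 and 0.126. With the mean level of keratinocyte genes as a covariate, chosen after seeing the data, limma called 2 genes, Zic1 and Mylk. Over 19 settings, the reported one and this one among them, the differences ran from 4.23 to 4.72 for Zic1, 2.53 to 3.82 for Mylk, 3.16 to 3.65 for Ppp1r14a, 2.39 to 2.94 for Actg2, 1.92 to 2.44 for Cnn1 and 0.64 to 1.83 for Acta2. The lower count thus does not show that the level of keratinocyte genes accounts for these differences.

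The remaining 10 lists were not called, at camera adjusted p from 0.225 to 0.802. Of 33 Hox genes Hoxa9 (1.97 ± 0.28, called in 8 of 19 settings) and Hoxc10 (1.24 ± 0.16) were higher, and adjusted over the list alone 3 were higher and 2 lower. Zic1 was the 1 called member of 25 trunk patterning genes (4 higher and 5 lower adjusted over the list alone). No member was called of 29 craniofacial factors, 29 chemokine, cytokine and complement genes, 20 endothelial, 22 leukocyte, 15 Schwann cell, 17 adipocyte, 14 bone, cartilage and tooth or 5 erythroid genes. Examples in these were Tfap2b at 4.36 ± 1.24 against 7.50 ± 1.86, Csf1r, a receptor of macrophages, at 9.88 ± 0.75 against 7.19 ± 1.14, Sox9 at 7.09 ± 0.45 against 8.30 ± 1.29 and Erbb3 at 5.62 ± 0.27 against 6.96 ± 0.41. For Hox, endothelial and leukocyte genes the median was below 0 while the mean and the test pointed up. Of 11 called named genes with further probe sets 3 had another one called the same way and 8 had none, among them Acta2, Ednrb, Myh11 and Trp63, whose other probe sets were not called.

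**Figure D2:**
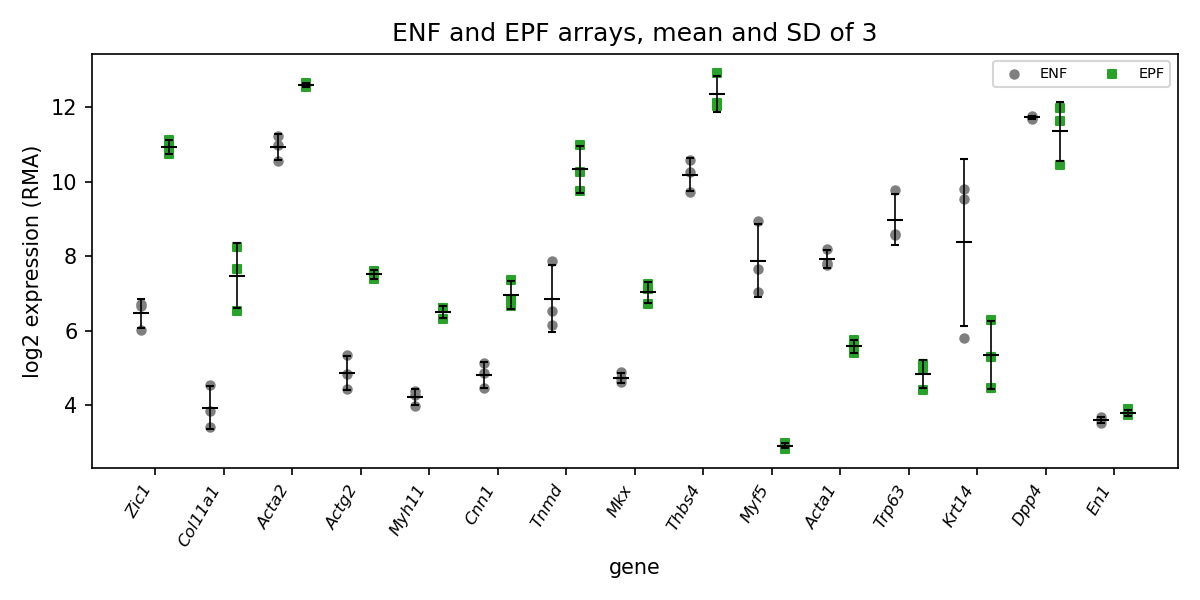
Log2 expression after RMA (vertical axis) of 15 genes in the ENF and EPF arrays, each point 1 array, with the mean and SD of 3. Smooth muscle, tendon and Zic1 values lie higher in EPF, Myf5, Acta1 and Trp63 lower, and the Krt14 values of ENF spread from 5.80 to 9.81.

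The second comparison set oral mucosa against cranial dermis within the Wnt1 lineage. Six2, a homeobox factor of craniofacial mesenchyme, was 8.25-fold higher in Oral, at 8.65 ± 0.16 against 5.60 ± 0.11 (log2 difference 3.04 ± 0.18, n = 3 per group), and Lhx8, a LIM homeobox factor of the jaw and palate, was higher by 2.82 ± 0.19. Tbx3 was higher by 2.64 ± 0.48, Adamtsl3 by 2.43 ± 0.33, Eya1, a transcriptional coactivator, by 2.42 ± 0.25, Alx1 by 2.31 ± 0.14, Pitx1 by 2.28 ± 0.14 and Aldh1a2, a retinoic acid synthesis enzyme, by 2.07 ± 0.27. Lgr5, a receptor for R-spondins, was 34.5-fold lower in Oral (5.45 ± 0.27 against 10.56 ± 0.15), Zic1 fell by 4.81 and Hoxd8 by 3.85. Clca3a1 fell by 3.78, Cyp4b1 by 3.59, Pcsk5, a proprotein convertase, by 3.44, Nrn1 by 3.42 and Ifi204, an interferon-inducible gene, by 3.34. Oral levels of Zic1 (3.23), Clca3a1 (3.65) and Ifi204 (3.70) were near background. Adjusted p in limma for these genes ran from 1.28e-05 for Six2 to 0.0229 for Tbx3. As the naming rule required, all 3 arrays of one group lay beyond all 3 of the other in each.

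Limma called 207 genes, 74 higher and 133 lower in Oral, of which 149 differed by at least 2-fold. At an unadjusted p under 0.05 there were 1507, and the groups did not overlap in 25.9% of genes, against 10% by chance. The count was 132 with dim genes left out, 1926 with array weights (1018 higher and 908 lower, which turns the balance) and 1795 with only the 6 arrays of both groups in the fit. It was 112, 113 and 111 without Cranial 1, 2 and 3 and 119, 115 and 129 without Oral 1, 2 and 3. The shared spread of the main fit took in the more variable Dorsal arrays, so genes not called here may still differ.

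Craniofacial patterning factors were higher in Oral as a group. Of 29 members 11 were higher and 18 not called (15 higher and 1 lower adjusted over the list alone), with a median of 0.48 and a camera adjusted p of 8.00e-18, which was 0.0466 with an estimated correlation. Besides Six2, Lhx8, Alx1 and Pitx1 they held, chosen after their values were seen, Pax3 (1.92), Shox2 (1.88), Tfap2a (1.85), Lhx6 (1.74), Dlx1 (1.06), Dlx2 (0.76) and Barx1 (0.60). Among 33 Hox genes 6 were lower and 27 not called (8 adjusted over the list alone). Hoxd8 and Hoxd9 (fell by 2.27) led, followed, chosen after their values were seen, by Hoxc4 (fell by 1.90), Hoxa2 (fell by 1.84), Hoxc5 (fell by 1.77) and Hoxd3 (fell by 1.40). The Hox median was 0.05, while the mean, -0.39, and the test were negative (adjusted p = 0.00113; 0.368 with an estimated correlation). Of 25 trunk patterning factors 2 were higher, Tbx3 and Meox2 (1.56 ± 0.30), and 3 lower, among them Zic1 and Irx2 (fell by 1.71), and the list was not called.

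Camera called the chemokine, proteoglycan, protease and glycoprotein lists lower in Oral, while few members were called and the called glycoproteins were higher. Of 29 chemokines, cytokines and complement genes 3 were lower, 1 higher and 25 not called (7 lower and 1 higher adjusted over the list alone), with a median of -1.18. Cxcl1, a neutrophil attractant, fell by 1.84, Ccl7, a monocyte attractant, fell by 1.61, and Cx3cl1 was higher by 1.41 ± 0.22. Of 12 small leucine-rich proteoglycans 3 were lower, among them Dcn, decorin (fell by 1.91, to 10.80 ± 0.03) and Epyc (fell by 1.95, Oral near background at 3.94), also 3 adjusted over the list alone. Of 27 proteases and inhibitors 2 were lower, Adamts15 (fell by 1.84, called in 9 of 18 settings) and Timp3 (fell by 0.88), and adjusted over the list alone 7 were lower and 2 higher. Of 29 matrix glycoproteins 2 were higher, Tnn, tenascin N (2.05 ± 0.13), and Thbs4 (1.70 ± 0.29), while the test of the list was negative (3 higher and 3 lower adjusted over the list alone). Camera adjusted p was 2.77e-09 for chemokines, 6.46e-06 for proteoglycans and for proteases and 0.0484 for glycoproteins, and with an estimated correlation 0.196, 0.196, 0.0466 and 0.573.

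A few pathway genes were lower, and their lists were called lower by camera at the preset correlation alone. Of 34 Wnt genes 4 were lower and 30 not called (6 lower and 3 higher adjusted over the list alone), among them Lgr5 and Wnt4 (fell by 1.90). Of 31 TGF-beta and BMP genes 2 were lower, Inhbb (fell by 2.67) and Bmp5 (fell by 2.58), and Bmp6 was higher by 1.22 ± 0.12 (3 lower and 1 higher adjusted over the list alone). Of 14 papillary genes Axin2, a Wnt target, was lower (fell by 1.10; 6 lower and 1 higher adjusted over the list alone), and of 15 general fibroblast genes Dcn (2 adjusted over the list alone). None of 32 immediate early genes was called, 0 also adjusted over the list alone, with a median of -0.11. Camera adjusted p was 0.00567 for Wnt, 0.00116 for TGF-beta and BMP, 3.31e-05 for papillary, 0.00487 for fibroblast and 0.0366 for immediate early genes. With an estimated correlation it was 0.322, 0.305, 0.0989, 0.381 and 0.573.

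The other 16 lists were not called, at camera adjusted p from 0.0677 to 0.928. Of 18 mural genes 3 were lower, among them Abcc9 (fell by 1.96) and Kcnj8 (fell by 1.51), subunits of 1 potassium channel, and Synm was higher (1.20 ± 0.18, Cranial near background at 3.95). Of 17 adipocyte genes Lpl, lipoprotein lipase, fell by 2.11 and Ebf2 was higher by 2.05 ± 0.16. Of 17 reticular genes Dcn and Ppp1r14a (fell by 1.69) were lower, of 19 keratinocyte genes Perp (fell by 1.43), and of 10 tendon genes Thbs4 was higher. No member was called of the collagen, cell cycle, endothelial, leukocyte, skeletal muscle, Schwann cell, melanocyte, bone, dermal papilla or erythroid lists. In the cell cycle list Cdc20 stood at 11.34 ± 0.27 in Oral and 10.66 ± 0.08 in Cranial, and in the skeletal muscle list Eno3 at 7.26 ± 0.28 and 6.18 ± 0.02. The median was above 0 while the test pointed down for the trunk, cell cycle, reticular, keratinocyte, endothelial, leukocyte, mural, melanocyte and dermal papilla lists. Of 22 called named genes with further probe sets 8 had another one called the same way and 14 had none, Lgr5, Tbx3, Eya1, Dcn and Bmp5 among the latter.

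The third comparison set ventral against dorsal dermis within the En1 lineage. Zic1 was 34.8-fold lower in Ventral, at 4.47 ± 0.43 against 9.59 ± 0.74 (adjusted p = 0.000101 in limma, lower in all 3 arrays). Hand2, a factor of limb, heart and branchial arch mesenchyme, was higher in all 3 Ventral arrays by 2.44 ± 0.27 (adjusted p = 0.0157). Lpar4, a lysophosphatidic acid receptor, fell by 1.30, Arap2 by 1.26 and Postn, periostin, a matrix protein, by 1.22 (adjusted p = 0.00547, 0.0262 and 0.0262), each lower in all 3 Ventral arrays. These 5 were all the genes called, 1 higher and 4 lower, each by at least 2-fold. Zic1 had another probe set called the same way, while Hand2, Lpar4 and Arap2 had other probe sets that were not called.

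At an unadjusted p under 0.05 there were 1555 genes, and the groups did not overlap in 10.1%, against 10% by chance. Limma called 0 genes with only these 6 arrays in the fit, 2 with the replicate number as a block, 8 after repeated quantile normalization, 12 over every probe set and 952 with array weights (443 higher and 509 lower). The count was 46, 161 and 9 without Dorsal 1, 2 and 3, and 25 and 3 without Ventral 1 and 3. The Dorsal arrays stood apart from each other in several genes: Adipoq, an adipocyte hormone chosen after its values were seen, was at 8.05, 4.07 and 7.49 in Dorsal 1 to 3, and Egr3 at 5.04, 4.16 and 9.47.

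Camera called 7 lists in this comparison, 5 higher and 2 lower in Ventral, and none with an estimated correlation (adjusted p = 0.656 for each). The directions turned with single arrays, at 1 higher and 4 lower without Dorsal 1, 5 and 7 without Dorsal 2, 5 and 0 without Dorsal 3, 3 and 3 without Ventral 2 and 5 and 4 without Ventral 3. Of 31 cell cycle genes none was called, with a median of 0.52 (adjusted p = 0.000477), and Mcm6 stood at 9.83 ± 0.04 in Ventral and 8.98 ± 1.58 in Dorsal. Of 25 collagens none was called, with a median of -0.32 (0.00253), and Col8a1 stood at 8.24 ± 1.41 and 10.21 ± 0.78. The other 5 were Hox genes (median 0.11, 0.0225), general fibroblast genes (-0.29, 0.0225), melanocyte (0.12, 0.0211), leukocyte (0.11, 0.0242) and skeletal muscle genes (0.13, 0.0425), with no member called in any. Adjusted over the list alone 3 Hox genes and 1 melanocyte gene were higher, 1 fibroblast gene was lower, and 0 cell cycle, collagen, leukocyte and skeletal muscle genes passed. Hoxc10 stood at 9.25 ± 0.40 and 8.03 ± 0.52, Hoxb6 at 5.71 ± 0.53 and 4.66 ± 0.28, Mlana at 6.14 ± 0.59 and 4.89 ± 0.48, and Lum, lumican, at 8.27 ± 2.27 and 9.84 ± 1.89. The leukocyte gene Laptm5 stood at 12.07 ± 0.08 and 10.31 ± 2.60, and its 4 other probe sets were not called. The remaining 20 lists had adjusted p from 0.0539 to 0.870, with Tnmd at 7.50 ± 1.04 and 10.02 ± 1.25 and Tgfbi at 11.15 ± 0.09 and 12.03 ± 0.17 among their members. Repeated quantile normalization left 1 list called.

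The fourth comparison set cranial dermis of the Wnt1 lineage against dorsal dermis of the En1 lineage, so body site and mouse line cannot be told apart. The Y-linked gene Eif2s3y parted these arrays too, so the sex of the cells also coincides with this comparison. Hoxc8, a homeobox gene of thoracic identity, was 71.7-fold lower in Cranial, at 4.57 ± 0.04 against 10.73 ± 0.68, Hoxa9 fell by 4.94 and Hoxc10 by 3.89. Ifi202b, an interferon-inducible gene, fell by 6.29, Eif2s3y, a gene of the Y chromosome, by 3.87, Apoe, apolipoprotein E, by 3.69, Rsrc2 by 3.02 and Aoc3 by 2.86. Sbspon was 42.2-fold higher in Cranial (9.52 ± 0.12 against 4.12 ± 0.63), and Mgp, matrix Gla protein, was higher by 5.13 ± 0.43. Ptgs2, cyclooxygenase 2, was higher by 4.75 ± 0.81, Mecom by 4.18 ± 0.26, Igf2 by 3.88 ± 0.70, Nr2f1, an orphan nuclear receptor, by 3.84 ± 0.28, Egr3 by 3.83 ± 1.01 and Igfbp2 by 3.56 ± 0.68. Cranial levels of Ifi202b (3.47) and Eif2s3y (3.33) and the Dorsal level of Nr2f1 (3.95) were near background. Egr3, at 5.04, 4.16 and 9.47 in Dorsal 1 to 3, ranged from 1.95 to 5.56 over 18 settings and was called in 13 of them (adjusted p up to 0.139). Adjusted p in limma ran from 6.91e-07 for Hoxc8 and Ifi202b to 0.0248 for Egr3, with all 3 arrays of one group beyond all 3 of the other, as the naming rule required.

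Limma called 3393 genes, 2037 higher and 1356 lower in Cranial, of which 1056 differed by at least 2-fold, 800 higher and 256 lower. Repeated quantile normalization gave 1817 higher and 1986 lower, and centring each array on its median gave 1421 higher and 5317 lower, so the balance of directions depends on the scaling. Every probe set gave 3816 higher and 4223 lower, and array weights 4896 and 5217, which also turn it. There were 5975 genes at an unadjusted p under 0.05, and the groups did not overlap in 35.5% of genes, against 10% by chance. The count was 6738 with centred arrays, 8039 over every probe set, 10113 with array weights and 1242 with only these 6 arrays in the fit. It was 1645, 2006 and 1768 without Cranial 1, 2 and 3 and 6148 without Dorsal 1. The shared spread of the main fit tends to understate that of the Dorsal arrays.

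Camera called the Hox list lower and the craniofacial list higher in Cranial at the preset correlation alone, with most members of each list not called. Of 33 Hox genes 13 were lower, 2 higher and 18 not called (14 lower and 2 higher adjusted over the list alone), with a median of -0.33. Chosen after their values were seen, Hoxc9 fell by 2.05 and Hoxa10 by 1.96, and the 2 higher members were Hoxa2 (1.68 ± 0.15, Dorsal near background at 3.35) and Hoxd3 (0.77 ± 0.17). Of 29 craniofacial factors 12 were higher, 1 lower and 16 not called (13 higher and 1 lower adjusted over the list alone), with a median of 0.21. Dlx2 was higher by 2.54 ± 0.15, Hand2 by 1.94 ± 0.27 and, chosen after their values were seen, Pax3 by 1.76 and Dlx1 by 1.65, and Foxd2 fell by 1.10. Camera adjusted p was 0.000163 for Hox and 8.15e-05 for craniofacial genes, and 0.468 for both with an estimated correlation.

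Immediate early and stress genes formed the other called list. Of 32 members 17 were higher, 2 lower and 13 not called (18 higher and 2 lower adjusted over the list alone), with a median of 0.84 and adjusted p = 7.40e-06 (0.468 with an estimated correlation). The difference between 3′ and 5′ probe sets of Actb and Gapdh, a sign of RNA quality, also parted these groups without overlap, at 2.83 ± 0.24 in Dorsal and 2.30 ± 0.08 in Cranial, and its part in this list was not tested. Myc was higher by 2.78 ± 0.28 and, chosen after their values were seen, Dusp1 by 2.56, Nr4a1 by 2.04 and Fos by 1.62, while Socs3, a feedback inhibitor of cytokine signalling, fell by 2.07 and Gadd45b by 1.90. With repeated quantile normalization 5 lists were called, 6 with the mean of probe sets, and 5 each without Dorsal 2 and without Dorsal 3.

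The other 24 lists were not called, at adjusted p from 0.0546 to 0.895, but held called genes. Of all genes 18.65% were called in this comparison, so called members alone do not set a list apart. Of 31 TGF-beta and BMP genes 9 were higher and 1 lower, with Bmp5 higher by 3.44 ± 0.21, Id1, a BMP target, by 2.91 ± 0.65, and Tgfbi lower (fell by 0.42, called in 5 of 18 settings, adjusted p up to 0.368). Of 34 Wnt genes 5 were higher and 4 lower, Rspo2 by 2.74 ± 0.45 and Sfrp1 by 2.64 ± 0.69, with Dkk2 (fell by 2.76) and Apcdd1 (fell by 2.06) on the other side. Of 25 trunk factors 5 were higher, among them Nr2f1 and Meox2 (2.05 ± 0.30), and 2 lower, Zic1 (fell by 1.56) and Zic4 (fell by 0.61). Of 17 adipocyte genes 4 were lower, among them Fabp4 (fell by 2.62) and Cd36 (fell by 1.76, Cranial near background at 3.44), and Zfp423 was higher (1.28 ± 0.27). Of 18 mural genes 4 were higher, among them Abcc9 (1.83 ± 0.33) and Kcnj8 (1.22 ± 0.21), and of 20 endothelial genes 3 were lower, among them Flt1 (fell by 1.36) and Kdr (fell by 0.73). Of 19 keratinocyte genes Perp was higher by 2.41 ± 0.16 and 3 were lower, among them Sfn (fell by 0.66) and Krt14 (fell by 0.46).

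Matrix and remaining lists were divided, and their called members too are to be read against the 18.65% of all genes called. Of 29 glycoproteins 4 were higher, among them Eln, elastin (1.55 ± 0.48), and Tnn (1.28 ± 0.13), and 3 lower, among them Thbs2 (fell by 1.08) and Vcan, versican (fell by 0.78). Of 27 proteases 2 were higher, Adamts15 (1.30 ± 0.38) and Serpinf1 (0.47 ± 0.14, called in 7 of 18 settings), and 2 lower, Adamts4 (fell by 1.99) and Mmp23 (fell by 1.08). Epyc (2.09 ± 0.19) was the 1 called proteoglycan and Col13a1 (0.39 ± 0.11) the 1 called collagen, with Dorsal levels near background at 3.79 and 3.85. Of the chemokine list Ccl7 was higher by 1.17 ± 0.21, and Cxcl2 fell by 2.79 and Csf1 by 1.22. Of the tendon list 3 were higher, among them Mkx (1.30 ± 0.37) and Egr1 (0.97 ± 0.20), of the reticular list 2, Mgp and Dlk1 (1.44 ± 0.27), and of the cell cycle list 2, Aurka (1.38 ± 0.42) and Nusap1 (1.37 ± 0.39). Of the papillary list Axin2 (1.13 ± 0.12) and Plxnc1 (0.78 ± 0.20) were higher and Apcdd1 lower, with 1 of 5 other Plxnc1 probe sets called the opposite way. Acan was higher by 1.88 ± 0.17 and Phex by 0.46 ± 0.14 (near background in both groups, called in 7 of 17 settings) in the bone, cartilage and tooth list, with Col2a1 lower (fell by 1.13), and Acan was the 1 higher dermal papilla gene, with 3 lower, among them Fgf10 (fell by 1.29) and Vcan. Scn7a was higher by 1.22 ± 0.20 in the Schwann cell list, where Egfl8 fell by 0.48 and Mal by 0.40, Dct fell by 0.52 in the melanocyte list, and Atp2a1 and Myod1 fell by 0.40 and 0.37 in the skeletal muscle list. None of the fibroblast, leukocyte or erythroid genes was called. Adjusted over the list alone, the calls of the cell cycle, collagen and skeletal muscle lists and of the higher proteases did not hold. The median levels of these groups differed by 0.21, while the median difference per gene was -0.06, so the directions of small differences depend on the scaling. Median, mean and test did not share a sign for the collagen, protease, trunk, papillary, fibroblast, mural and melanocyte lists. Of 41 called named genes with further probe sets 18 had another one called the same way, 22 had none, and Plxnc1 had 1 called the opposite way.

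**Figure D3:**
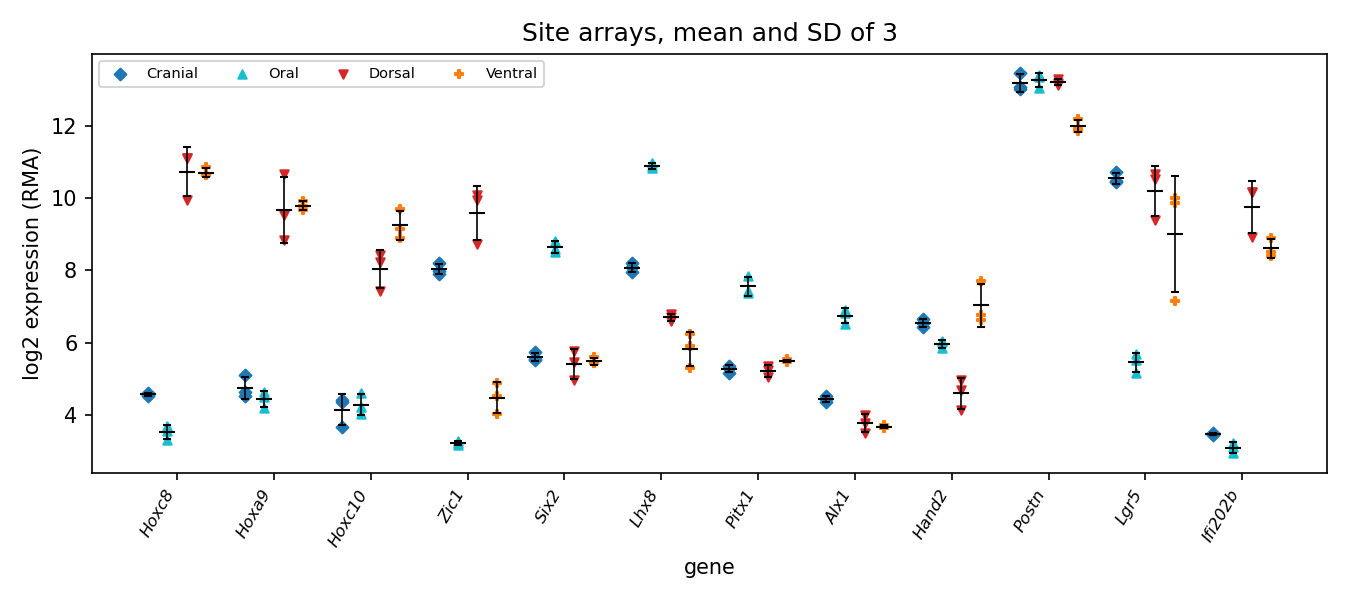
Log2 expression after RMA (vertical axis) of 12 genes in the Cranial, Oral, Dorsal and Ventral arrays, each point 1 array, with the mean and SD of 3. Hoxc8 lies near 10.7 in Dorsal and Ventral and at 4.57 and 3.52 in Cranial and Oral, and Zic1 lies at 9.59 in Dorsal, 8.04 in Cranial, 4.47 in Ventral and 3.23 in Oral.

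The other pairs of sites across the 2 lines were summarised by count and leading genes. In these pairs too, body site and mouse line cannot be told apart, and Y-linked Eif2s3y parted the lines, so sex may differ as well. In Oral against Dorsal limma called 3065 genes, 1918 higher and 1147 lower, led by Angptl1 (4.99 ± 0.32), Sbspon (4.68 ± 0.43) and Nr2f1 (4.66 ± 0.28) above and Hoxc8 (fell by 7.22), Ifi202b (fell by 6.68) and Zic1 (fell by 6.37) below. Repeated quantile normalization gave 1783 higher and 1756 lower, and centring gave 1338 and 4045, while every probe set gave 3465 and 3699. Oral levels of Hoxc8 (3.52), Ifi202b (3.08) and Zic1 (3.23) and Dorsal levels of Angptl1 (4.03) and Nr2f1 (3.95) were near background. The count was 5623 without Dorsal 1 and 1770 and 2025 without Oral 2 and Oral 3. In Oral against Ventral 2665 genes were called, 1881 higher and 784 lower, led by Egr3 (5.75 ± 1.01), Angptl1 (5.42 ± 0.32) and Nr2f1 (5.21 ± 0.28) above and Hoxc8 (fell by 7.20), Ifi202b (fell by 5.53) and Hoxa9 (fell by 5.36) below, with Ventral levels of Egr3 (3.94), Angptl1 (3.61) and Nr2f1 (3.41) near background. Repeated quantile normalization gave 1608 and 1497, and centring 1367 and 2822, and the count was 1758 and 1420 without Oral 1 and Oral 2 and 1719 without Ventral 2. In Cranial against Ventral 3251 genes were called, 2123 higher and 1128 lower, led by Egr3 (6.11 ± 1.01), Sbspon (5.25 ± 0.43) and Ptgs2 (4.97 ± 0.81) above and Hoxc8 (fell by 6.14), Ifi202b (fell by 5.14) and Hoxc10 (fell by 5.10) below, with Ifi202b near background in Cranial (3.47) and Egr3 in Ventral. Repeated quantile normalization gave 1802 and 1933, and centring 1690 and 4534. The count was 1695, 2093 and 1641 without Cranial 1, 2 and 3, and 2067 and 2144 without Ventral 2 and Ventral 3. All 3 arrays of one group lay beyond all 3 of the other in each of these genes, as the naming rule required.

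EPF and Dorsal cells carry the same line, tissue and sort gate in the labels and differ in the labelled age, so the 2 groups were compared as a check. Pi16, a gene of adventitial fibroblasts, was higher in EPF by 8.61 ± 0.22 (13.80 ± 0.30 against 5.19 ± 0.24), Cd34, a surface marker of dermal fibroblasts, by 8.41 ± 0.57, and Cilp by 7.71 ± 0.43. Cxcl5, a chemokine, was lower in EPF (fell by 7.54), as were Tnc, tenascin C, and Htr1b, a serotonin receptor (fell by 5.88 and 5.73), with EPF levels of Cxcl5 (3.47) and Htr1b (3.90) near background. Adjusted p in limma ran from 4.91e-05 for Pi16 to 0.00111 for Htr1b, with all 3 arrays of one group beyond all 3 of the other, as the naming rule required. Chosen after their values were seen, Dpp4 was higher by 6.57, Tek by 6.24 and Hspa1a, a heat shock gene, by 5.72, while Mki67 fell by 5.21 (adjusted p = 0.000273, 0.000177, 0.000523 and 0.00776). Limma called 3055 genes, 1974 higher and 1081 lower, of which 2350 differed by at least 2-fold. Repeated quantile normalization gave 1745 higher and 1914 lower and centring 1589 and 1595. The count was 1726, 1610 and 1474 without EPF 1, 2 and 3 and 1940 without Dorsal 2, 5780 over every probe set, 6657 with array weights and 5678 with all 18 arrays in the fit. Labelled age, and any difference in how the 2 sets of arrays were handled, cannot be told apart from the groups here.

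Control probe sets and RNA quality signs differed between the sets. Poly-A spike-in probe sets, which report RNAs added before labelling, averaged 13.63 ± 0.32 in ENF, 12.20 ± 0.54 in EPF and 7.04 ± 0.54 in the 12 site arrays, and hybridization controls averaged 11.86 ± 0.29, 10.81 ± 0.10 and 9.56 ± 0.25. The difference between 3′ and 5′ probe sets of Actb and Gapdh, which grows as RNA degrades, averaged 3.08 ± 0.16 in ENF, 3.19 ± 0.38 in EPF and 2.46 ± 0.28 in the site arrays, with 2.83 ± 0.24 in Dorsal and 2.30 ± 0.08 in Cranial.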

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

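The tests of labelling, of other cell types, of mural cells, of keratinocytes, of dilution, of the 2 mouse lines and of sex were chosen only after the results were seen; the counts over other splits of the samples were planned. The actomyosin and YAP target list and its bounds were written after the EPF against Dorsal difference was known but before the list's own value was seen. By their bounds, also written after the results were seen, the mural cell, keratinocyte, labelling and Eif2s3y tests would count for, and the array processing test against, their explanations. The labelling and Eif2s3y tests were left undecided because they coincide with the groups or lines, and the other 3 were later set to undecided because they use the genes that define the pattern. A test of RNA quality was also run for the EPF and ENF arrays, with the 3′ to 5′ difference of Actb and Gapdh at 3.19 ± 0.38 and 3.08 ± 0.16, and was replaced by the dilution test once that value had been seen.

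Signal in data that no comparison used stood out in the control probe sets. The poly-A spike-in mean was higher in the EPF and ENF arrays than in the site arrays by 5.88 on the log2 scale, and higher in ENF than in EPF by 1.43. For the hybridization controls these differences were 1.78 and 1.05.

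Every comparison had 3 arrays against 3, which gives 10 splits, too few for a share under 0.05. The other splits mix arrays of both groups, so any difference between the groups adds to their spread and tends to lower their counts. A low count there does not tell one source of the difference from another. In each case the number of splits that called as many genes, the real split included, is given with the real count and the highest other count. EPF against ENF gave 1 split, with 56 and 1; Oral against Cranial 1, with 207 and 0; Cranial against Dorsal 1, with 3393 and 0; and Oral against Dorsal 1, with 3065 and 0. Oral against Ventral gave 1 split, with 2665 and 0, Cranial against Ventral 1, with 3251 and 0, and EPF against Dorsal 1, with 3055 and 0. Ventral against Dorsal gave 4 splits, with 5 and 62. There, other splits of the 6 arrays called several times more genes than the real one. The real count of 5 came from the fit of all site arrays. Its shared spread took in the Cranial and Oral arrays, with a median SD per gene of 0.104 and 0.134, against 0.281 in Dorsal. With only the 6 arrays in the fit, limma called 0 genes for the real split. The split counts may reflect this shared spread, so they cannot tell whether the samples hold a structure other than the body site.

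The first pattern is the difference between EPF and Dorsal cells, which share line, tissue and sort gate in the labels. Endothelial, leukocyte or keratinocyte cells in the Dorsal arrays would lower those lists in EPF. The lowest of the 3 medians was 0.10, which argues against such cells in the Dorsal arrays as a source. The keratinocyte list lay higher in EPF, with a median of 1.05 and 14 of 19 members higher. Other cells in the EPF arrays were not tested as a source. If Dorsal cells were in a spread, growing state as in culture, actomyosin and YAP target genes would be lower in EPF. Their median was -0.28 with 11 of 16 members lower and a median absolute deviation of 1.11, so the test left this open. A difference in labelling or hybridization may also contribute, since the spike-in level was higher in EPF than in Dorsal by 5.49, but it coincides with the groups and cannot be told apart from them, nor can the labelled age, which was not tested.

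The second pattern is the higher smooth muscle and lower keratinocyte signal in EPF against ENF. Dilution of ENF fibroblast RNA by other cells would raise fibroblast genes in EPF about as much as smooth muscle genes. The medians were 0.24 (13 of 15 fibroblast genes higher) and 1.16, which argues against dilution as the whole cause for the smooth muscle genes. A smaller part of dilution in the difference is not excluded. Vessel mural cells among the EPF cells were not tested by the median of 1.06 for 8 pericyte markers, none of them called, beside 1.31 for 10 contractile genes, since these 18 genes are the list that defined the pattern. Keratinocytes among the ENF cells were likewise not tested by the 84.2% of the keratinocyte list with a difference below 0, which restates the pattern, and the sort as EpCAM negative in the labels should remove many of them; Krt5, chosen after its values were seen, was at 9.64, 11.73 and 11.34 in ENF 1 to 3 and at 9.72, 6.14 and 7.43 in EPF 1 to 3, and the 2 Epcam probe sets disagree. Both, and expression of smooth muscle genes by the fibroblasts themselves, stay open. Control probe sets also parted the groups without overlap. Poly-A spike-ins ran from 13.36 to 13.98 in ENF and from 11.63 to 12.70 in EPF. Hybridization controls ran from 11.64 to 12.19 in ENF and from 10.72 to 10.92 in EPF. A difference in how the arrays were handled coincides with the groups and was not tested.

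The third pattern is that Ifi202b and Eif2s3y separated the 12 arrays of the En1Cre line from the 6 of the Wnt1Cre line, the lowest En1Cre array lying above the highest Wnt1Cre array by 4.91 for Ifi202b and by 1.48 for Eif2s3y. Sex as the source of the Ifi202b difference would make Ifi202b follow Eif2s3y within the En1Cre groups with a slope near 1, while the slope over the 12 arrays was 0.0546 ± 0.137 (SE), which argues against it. No label names a processing batch that follows the line; among the site arrays the poly-A spike-ins overlapped between the lines, and the hybridization controls alone parted them, with means of 9.30 in Cranial, 9.41 in Oral, 9.77 in Dorsal and 9.75 in Ventral, far less apart than Ifi202b. The gap of 4.91 cannot decide on a process that touched the Wnt1Cre arrays alone, so this was left undecided. Genetic background coincides with the line for both genes and cannot be told apart from lineage and body site here. For Eif2s3y, a gene of the Y chromosome, Xist values seen afterwards bear on sex. The Cranial mean of Eif2s3y was 3.33, near background, beside high Xist, as in female cells. The Dorsal arrays held both signals, as in a mix of female and male cells. This argues against lineage or body site alone as the source of the Eif2s3y difference between Cranial and Dorsal.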

How the results depend on the processing

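The tests without ENF 1 and EPF 2 together, those with a keratinocyte covariate and those with Atxn1 left out of the reticular list were chosen only after the results were seen; the other alternatives were planned. Of 195 alternative values of the counts and similarities, 112 stayed within the limit set for them (1.5 times for counts) and 83 moved beyond it. Unless a reason is given, the cause was not tested.

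Testing every probe set raised the called number to 12 for Ventral against Dorsal, 8039 for Cranial against Dorsal, 7164 for Oral against Dorsal, 5763 for Oral against Ventral, 7346 for Cranial against Ventral and 5780 for EPF against Dorsal. More features were tested there, 45037 probe sets against 18193 genes, and the share called was no higher than among genes. The rise in these counts is therefore no sign of a stronger difference. The same change gave 45 instead of 56 for EPF against ENF. Array weights gave 1926 for Oral against Cranial, 952 for Ventral against Dorsal, 10113 for Cranial against Dorsal, 8963 for Oral against Dorsal, 7724 for Oral against Ventral, 8854 for Cranial against Ventral and 6657 for EPF against Dorsal. With only the 2 groups in the fit the counts were 1795, 0 and 1242 for Oral against Cranial, Ventral against Dorsal and Cranial against Dorsal, and 1065, 4925 and 6684 for Oral against Dorsal, Oral against Ventral and Cranial against Ventral. Limma called that 0 where 1555 genes had an unadjusted p under 0.05 in the fit of 12 arrays. With all 18 arrays in the fit there were 460 genes for EPF against ENF (51 of the 56 among them) and 5678 for EPF against Dorsal. An intensity trend with robust eBayes gave 88 for EPF against ENF, and leaving out dim genes gave 132 for Oral against Cranial.

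Centring arrays on their median gave 6738 for Cranial against Dorsal, 5383 for Oral against Dorsal, 4189 for Oral against Ventral and 6224 for Cranial against Ventral, and repeated quantile normalization gave 8 for Ventral against Dorsal. A 2-fold minimum left 1056, 1148, 1056 and 1088 for Cranial against Dorsal, Oral against Dorsal, Oral against Ventral and Cranial against Ventral, as fewer genes can pass it. Without ENF 1 and EPF 2 there were 4 genes for EPF against ENF, with 2 arrays against 2, and with the keratinocyte covariate 2, Zic1 and Mylk. With dim genes left out, the distance between arrays (1 minus r) rose from 0.0165 to 0.0342 within groups, from 0.0301 to 0.0701 between groups of a set and from 0.0963 to 0.229 between the sets.

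With the replicate number as a block, limma called 21 genes for EPF against ENF and 2 for Ventral against Dorsal. The numbers do not pair the arrays: no comparison had all 3 same-number correlations over 0.1, and the values for EPF against ENF were -0.08, -0.11 and -0.08. A block that pairs nothing costs degrees of freedom, so the lower counts say nothing on the size of the effects. Only equal numbers were used as pairs in the fits. For EPF against ENF the highest correlation between different numbers was 0.246, so a pairing under other numbers is not excluded.

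With an estimated correlation 1 of 17 lists stayed called for EPF against ENF, 2 of 11 for Oral against Cranial, 0 of 7 for Ventral against Dorsal and 0 of 3 for Cranial against Dorsal. Repeated quantile normalization gave 1 list for Ventral against Dorsal and 5 for Cranial against Dorsal, and the mean of probe sets 6 for Cranial against Dorsal. Leaving out Atxn1, which a wrong match of the name Sca1 had put into the reticular list, kept the counts of 17, 11, 7 and 3.

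Leaving out 1 array at a time, counts ran from 4 to 130 genes for EPF against ENF (4 without EPF 2, 9 without EPF 3, 37 without EPF 1, 130 without ENF 3), 111 to 129 for Oral against Cranial (lowest without Cranial 3), and 3 to 161 for Ventral against Dorsal (3 without Ventral 3, 9 without Dorsal 3, 25 without Ventral 1, 46 without Dorsal 1, 161 without Dorsal 2). They ran from 1645 to 6148 for Cranial against Dorsal (without Cranial 1 and Dorsal 1), 1770 to 5623 for Oral against Dorsal (without Oral 2 and Dorsal 1), 1420 to 2270 for Oral against Ventral (lowest without Oral 2), 1641 to 2350 for Cranial against Ventral (lowest without Cranial 3) and 1474 to 4061 for EPF against Dorsal (lowest without EPF 3). For lists the ranges were 16 to 17, 9 to 12, 5 to 12 (12 without Dorsal 2) and 3 to 5 (5 without Dorsal 2 or Dorsal 3) in the 4 main comparisons in the order of the report.

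Among named genes, 3016 alternative values stayed on their side of the threshold, 92 passed it, 194 no longer passed it and 2 were called in the direction opposite to the reported value; with 1 array left out the numbers were 1579, 20, 206 and 1. All 3 such calls were in the Cranial vs Dorsal Epcam value, not called at 0.03, and called at -0.35 with the mean of probe sets, -0.31 with array weights and, over arrays left out, -0.45 (without Dorsal 1) to 0.30. Counted whether called or not, 30 of 301 named results changed sign in at least 1 setting, among them EPF vs ENF Epcam (-1.03 to 1.15), Ventral vs Dorsal Lum (-2.24 to 0.34) and Cranial vs Dorsal Acta2 (-0.20 to 0.83) and Pdgfra (-0.27 to 0.83), and 0 of the 30 were called in the report. Dim signal limits genes such as En1, whose group means of 3.41 to 4.06 lie near the lower quartile of the arrays, so their small differences say little.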

Other observations

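Xist and the Y-linked gene Eif2s3y were read in each array, chosen after their values were seen. ENF 1 and EPF 2 had Xist at 4.98 and 5.20 with Eif2s3y at 8.16 and 8.45. In the Dorsal arrays Xist was at 10.88 to 11.33 while Eif2s3y averaged 7.20 ± 0.52, so both were present in the same arrays. In the 3 Cranial arrays Eif2s3y averaged 3.33 ± 0.03 with Xist at 11.14 to 11.33.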
